A study of Homo sapiens with 2 samples.

How the data were processed

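AM-tag ChIP-seq was made from F36P cells with AM-ERG or with the empty vector, 1 library each. Per the labels' protocols, 10000000 cells per sample were fixed in 1% formaldehyde, chromatin was digested with micrococcal nuclease for 20 minutes, and 10 µg of chromatin was used per precipitation. Per the submitters' processing notes, the tools named are Bowtie2, MACS2 and deepTools and the build is hg38; versions and settings are not given in the sources used here. The deposited file analysed here is a headerless list of MACS2 narrow peaks. The authors' values for each peak are a score, a fold enrichment (a ratio to local background at the summit), the −log10 of the p-value and of the q-value, and the summit's offset in bp. The largest q in the list was 0.0474, below a threshold of 0.05. The peak names carry the name of 1 alignment. Which library that was, and whether the other served as its control, is not given in the sources used here, so the peaks are described as those of the deposited list. The labels give 1 library per group, and a peak's values were used only to describe, rank or filter peaks within this list.

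From each peak's fold and −log10 p, the whole-number pileup and the local background at the summit were recovered, taking the fold as pileup plus 1 over background plus 1 and the p as a Poisson tail. This gave back the deposited p for 100% of the 1645 peaks, with a largest error of 0.000834 against a tolerance of 0.001 in log10 p. Among peaks of chromosomes 1 to 22 and X with a low background, 46.9% of backgrounds were whole multiples of 0.704 fragments (tolerance 0.0002), where other step sizes gave a median of 0%. Such steps arise in MACS2 when a separate control library is scaled down to the treatment, here from 1.42 times its size. The lowest background was 1.92 fragments, shared by 141 peaks. These are relative depths. The number of reads per library was not recovered, and regions with more copies or more mappable reads have a higher background and so reach significance at a lower fold.

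Genes were taken from RefSeq on GRCh38.p14, the assembly of the peaks' build, with the start, end and biotype of 59792 genes, of which 19974 were protein-coding on chromosomes 1 to 22 and X. All 449 genes of the fixed lists were matched. The table gave neither strand nor exons, and no genome sequence was used here. The planned measure of promoters was therefore replaced by a summit within 1 kb of either end of a protein-coding gene, and exons and introns were not separated. Planned searches for ETS, GATA, RUNX and other motifs, backgrounds matched on GC content and the test of peaks on ERG exons were not run. Random placement drew 1000 sets on the same chromosomes, leaving out intervals of over 1 Mb without an annotated gene in place of assembly gaps. For gene lists, a permutation test was used: genes with a summit in the gene or within 10 kb were counted against 10000 random lists of the same size matched on 10 bins of gene length. These tests were two-sided, with Benjamini-Hochberg adjustment. They treat genes as the units and say nothing of replicate libraries. Intervals of shares are Wilson intervals and those of densities exact Poisson intervals, at 95%, and both cover counting error only.

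The named genes followed a rule set before the data were examined: the genes nearest to the 20 peaks of highest significance, up to 6 genes per list by significance, the 10 genes with most peaks (ties by shorter length, set after the data were seen), and 12 fixed genes. Exceptions are named where they occur, and a few genes that the rule selects are not reported here. Peaks on scaffolds, alternate loci and mitochondrial DNA were left out of the analysis by gene. Alternatives covered the threshold, the window, the matching and the placement, and 3 kinds of setting were added after seeing the data: matching also on gene density, leaving out the 268 peaks whose background exceeded 2 times the median (7.04 fragments), and keeping the upper 50% of peaks by fold. The limit of 7.04 fell on a step of the background, so peaks at the limit were kept or left out by rounding.

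Tested on simulated data, the recovery returned 300 of 300 peaks. The simulated backgrounds stopped well short of the highest in the list (3121.5 fragments), so recovery at the highest backgrounds was not simulated. A list of 30 genes among the 19974 with no enrichment was called in 5 of 100 simulations at an unadjusted 0.05, and one with 4-fold enrichment in 97 of 100. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.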

Results

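F36P is a human erythroleukaemia cell line. The cells carried either an empty MSCV-PIG retroviral vector (Vector) or the same vector with ERG, an ETS-family transcription factor, joined to an AM tag (AM-ERG). Both were selected with puromycin at 1 µg/ml for 4 days, and chromatin was precipitated with an antibody to the tag, so that the experiment asks where tagged ERG sits on chromatin. The labels list 1 library of each kind. The measurement analysed here was 1 list of 1645 peaks on 44 sequences of hg38. No replicate error could be given for any value, no test between AM-ERG and Vector was possible, and every comparison below is between positions or genes within this list. Fold enrichments are the authors' values over local background.

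Peaks had a median width of 390 bp (271 to 1680 bp) and a median fold enrichment of 4.62 (1.27 to 23.3). The read depth of the libraries was unknown. The pileup recovered at the summits had a median of 21 fragments (10 to 3977). How weak a binding site the list could show was not tested. The analysis by gene used the 1564 peaks on chromosomes 1 to 22 and X.

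Where the peaks lay relative to genes was compared first. Most were at the ends of protein-coding genes. Of the 1564 peaks, 966 had their summit within 1 kb of such an end, which was 61.8% (95% Wilson interval 59.3 to 64.1%, counting error only). Random placement of the same peaks on the same chromosomes gave 3.37%, so the share was 18.3 times the random one, and 0 of 1000 placements came as high (highest 4.80%). With placement 10 to 100 kb from each peak the ratio was 10.0. The annotation used here gave no strand, so starts and stops of genes were counted together. The summits at gene ends were a median of 186.5 bp from the end, 525 of them (54.3%) within 200 bp, and 665 (68.8%, 65.9 to 71.7%) on the gene's side of it. A further 256 peaks (16.4%) were inside genes away from their ends, where random placement put 44.5%. Another 65 (4.16%) were outside genes and within 10 kb, and 277 (17.7%, random 44.1%) were farther away. Those 277 had a median fold enrichment of 3.41 and a median local background of 7.74 fragments, against 4.87 and 3.45 at gene ends. They include runs of raised background. One run, of 15 peaks on chromosome 19 (24930048 to 27145077), had a median background of 24.6 fragments. Another, of 60 peaks on chromosome 21 with the ribosomal DNA, lay a median of 577 kb from a gene end, with a median background of 42.9 fragments.

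**Figure D1:**
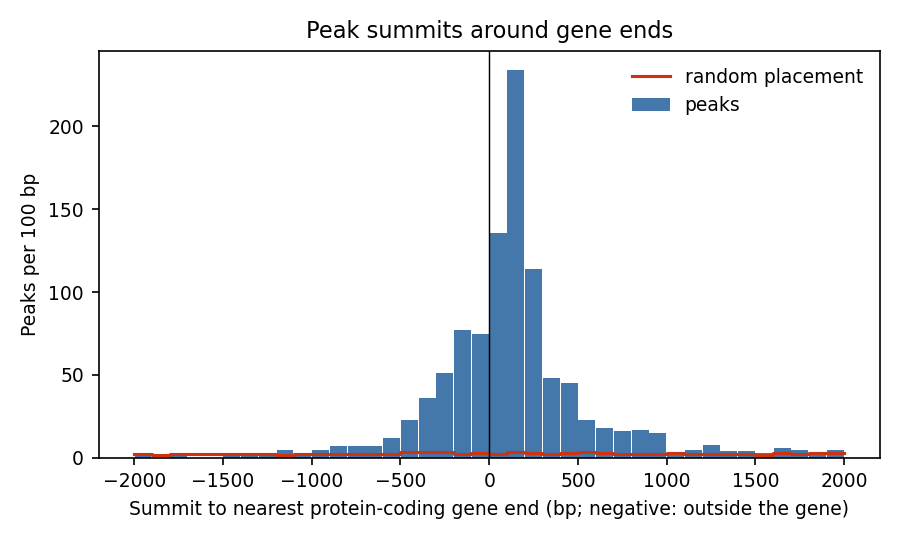
Number of peak summits per 100 bp (vertical axis) against distance to the nearest protein-coding gene end in bp (horizontal axis, negative outside the gene); bars are the peaks and the line is what random placement gave. The tallest bar, with 234 peaks, is 100 to 200 bp inside the gene.

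Of the 20 peaks with the highest fold enrichment, 14 were at gene ends. The highest of all lay in RARA, which encodes retinoic acid receptor alpha, at chromosome 17, 40322644 to 40323194, 13.7 kb from the nearest gene end, with a fold enrichment of 23.3. CTTN, which encodes the actin-binding protein cortactin, followed at 15.7, then MIER1 at 15.3, at a peak shared with an end of DNAI4, and MYL12B, a myosin regulatory light chain gene, at 14.4. SIRT6, a NAD-dependent deacylase gene, had a fold of 12.3 at a peak 73 bp from its end that also lay within 1 kb of an end of ANKRD24. BBC3, which encodes the pro-apoptotic protein PUMA, was the gene nearest to a peak of 11.8 at a distance of 11.4 kb. PLEKHG2 and EPOR each had a fold of 11.2. By significance, 11 of the top 20 peaks were of another kind, over 100 kb from any protein-coding gene or on an unplaced scaffold. Their fold enrichments were 1.27 to 3.03 on local backgrounds of 146 to 3121 fragments, and the genes nearest to those on chromosome 1 were H3-7 and LINC02798, the closest of them 640 kb away. The remaining peak of the top 20, near CCDC200 on chromosome 17, had a fold of 4.79 on a background of 32.4 fragments.

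At the genes fixed for inspection whatever their values, ERG and EPOR stood among the strongest sites. ERG itself, on chromosome 21, held 1 peak at 38376435 to 38376927, inside the gene and 9351 bp from its lower-coordinate end, with a fold of 11.9 and a pileup of 53 fragments. EPOR, which encodes the erythropoietin receptor, had 2 peaks. The stronger, at chromosome 19, 11383987 to 11384766, had its summit 59 bp inside the gene, a pileup of 97 fragments and a fold of 11.2. The weaker had a fold of 4.75. The local background at the stronger EPOR peak was 7.74 fragments, within a segment where the median background was 2.20 times that of all peaks on chromosomes 1 to 22 and X. LYL1, a basic helix-loop-helix factor of blood stem cells, had 2 peaks, of 10.1 fold at the neighbouring end of TRMT1 and of 6.68 fold 70 bp from its own end. FLI1, the closest ETS relative of ERG, had 1 peak of 4.77 fold. No peak was listed in or within 10 kb of HDAC7, the histone deacetylase named in the series title, and the nearest was 285 kb away. The same held for the erythroid factors GATA1 (286 kb) and KLF1 (58.9 kb) and for GATA2 (63.2 kb), RUNX1 (1271 kb), TAL1 (1412 kb), LMO2 (160 kb) and SPI1 (16.1 kb).

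Gene lists fixed before the data were examined were then compared with random lists. Erythropoietin, JAK and STAT pathway genes and ETS-family genes had peaks more often than random genes of like length. So did the ribosomal protein genes of the fixed list, while wider families with RPS and RPL symbols, described below, did not pass. In the pathway list 13 of 31 genes had a peak in the gene or within 10 kb (2.93 expected, ratio 4.43), in the ETS list 11 of 27 (2.83 expected, ratio 3.89) and in the ribosomal protein list 10 of 31 (2.75 expected, ratio 3.63). Of the 77 list genes with a peak, 25 (32.5%) had their most significant peak within 1 kb of an end of another gene. Over all 19974 protein-coding genes 1913, or 9.58%, had a peak by this measure. In a two-sided permutation test against 10000 random lists, with Benjamini-Hochberg adjustment over the 19 lists, the adjusted p was 0.0019 for the pathway and for the ETS genes, from the smallest p these draws can give (0.0002), and 0.0038 for the ribosomal protein genes. Among the upper 50% by significance of the 1564 peaks on chromosomes 1 to 22 and X the ETS list did not pass (4 genes, adjusted permutation p = 0.448). Among the upper 50% of peaks by fold, a setting chosen after seeing the data, neither the ETS nor the ribosomal protein list did (6 genes and an adjusted permutation p = 0.0503 for each), while their ratios were 3.67 and 4.06. The pathway list passed in all 8 alternatives, with adjusted p from 0.0019 to 0.0038.

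In the pathway list, strong peaks by significance were at EPOR, BCL2L1 (fold 10.0), PTPN6 (9.10), PTPN11 (7.45) and STAT3 (6.29). BCL2L1 encodes the anti-apoptotic protein BCL-XL, and PTPN6 and PTPN11 encode the phosphatases SHP-1 and SHP-2. The strongest peaks at EPOR, BCL2L1 and STAT3 were within 1 kb of the gene's end, while those of PTPN6 and PTPN11 were 2032 and 9469 bp away from it. PTPN11 had a second peak of 3.23 fold 12 bp from its end. JAK2, chosen for mention after its values were seen, had a peak of 3.36 fold 492 bp inside the gene, on a background of 13.6 fragments. That background lay in a segment of chromosome 9 with 3.25 times the median background. STAT5A and STAT5B, also chosen for mention after their values were seen, were among the listed genes without a peak. Their nearest peaks were 76.3 and 99.9 kb away.

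In the ETS list, ERG was followed by ETS1 (fold 7.86), ELF2 (4.76), ETV2 (5.94), FLI1 and ELK4 (4.68). The peaks of ETV2 and ELK4 were at gene ends, 52 and 741 bp away. The strongest peaks of ERG, ETS1, ELF2 and FLI1 were inside the gene, 9351 to 38841 bp from its ends, and ELF2 had a second peak of 2.65 fold 913 bp from its end. The ribosomal protein genes with the most significant peaks were RPS19 (fold 8.03), RPS27 (6.70), RPL4 (6.69), RPL8 (4.43), RPS14 (5.17) and RPL15 (5.98). The most significant peak counted for RPL8 lay 2497 bp outside the gene at an end of ZNF34, and a weaker one of 3.11 fold was 246 bp from its own end. The RPL4 peak also lay at an end of ZWILCH and the RPS27 peak at an end of RAB13.

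**Figure D2:**
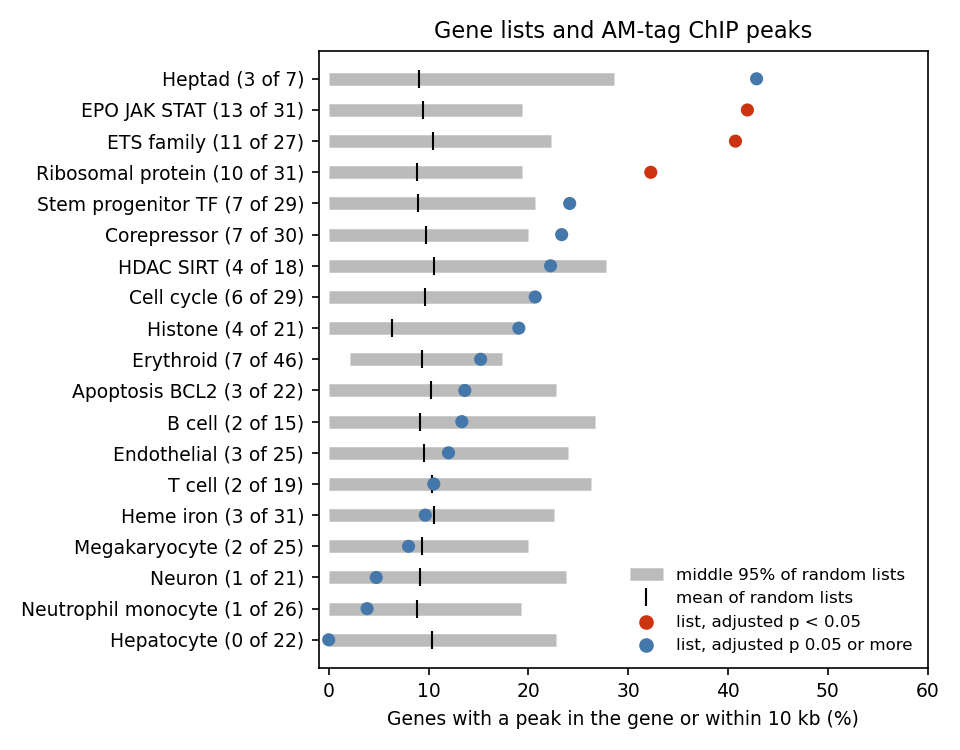
Percentage of genes of each fixed list with a peak in the gene or within 10 kb (horizontal axis); points are the lists, grey bars the middle 95% of random lists and ticks their mean. The pathway, ETS and ribosomal protein lists (41.9, 40.7 and 32.3%) are marked as past the threshold.

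Several lists tied to ERG or to blood stem cells had ratios above 1 without passing the test. The heptad of stem cell factors had peaks at 3 of 7 genes (ERG, LYL1 and FLI1, 0.631 expected, adjusted permutation p = 0.126). The stem and progenitor factors had 7 of 29 (2.61 expected, adjusted permutation p = 0.123), led by ERG, LYL1, HHEX (fold 11.5), GFI1B (4.07), FLI1 and BMI1 (4.35). The corepressor list had 7 of 30 (2.92 expected, adjusted permutation p = 0.126), among them SIN3B (7.01), CBFA2T3 (8.07), RCOR1 (5.17), EZH2 (4.98) and HDAC1 (4.05). The SIN3B peak was 8606 bp from the gene, at an end of F2RL3. Histone deacetylase and sirtuin genes had 4 of 18 (ratio 2.11, adjusted permutation p = 0.434), namely SIRT6, HDAC1, SIRT3 (4.02) and SIRT7 (4.18). The SIRT3 peak also lay at an end of PSMD13 and the SIRT7 peak at an end of PCYT2.

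Erythroid genes had peaks at 7 of 46 (4.28 expected, ratio 1.64, adjusted permutation p = 0.445). Besides EPOR they were led by CBFA2T3, NFE2 (7.53), ZFPM1 (5.90), GFI1B and LDB1 (4.66), which encode nuclear factors or cofactors. The LDB1 peak also lay at an end of PPRC1. Heme and iron genes had 3 of 31 (3.26 expected, adjusted permutation p = 1): PCBP1 (6.33), SLC25A38 (7.11) and FTH1 (4.58), of which the SLC25A38 peak lay at an end of RPSA and the PCBP1 peak also at an end of ASPRV1. Cell cycle genes had 6 of 29 (2.79 expected, adjusted permutation p = 0.248), which were RBL2 (7.19), PCNA (4.98), E2F2 (5.17), MCM2 (4.65), CCND3 (4.20) and CDKN2C (4.68). The PCNA peak was 1833 bp away at an end of TMEM230, and the CDKN2C peak also lay at an end of FAF1. Histone genes had 4 of 21 (1.33 expected, adjusted permutation p = 0.207), at H2BC12 (6.11), H2AZ1 (4.72), H2AC18 (3.32) and H3-3A (4.82). The H2BC12 peak also lay at an end of H2AC12, and the H2AC18 peak was 7924 bp away at an end of H2AC19. BCL2-family genes had 3 of 22 (2.26 expected, adjusted permutation p = 1), at BCL2L1, BID (6.06) and BAD (5.62), the last also at ends of PLCB3 and GPR137.

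Markers of 7 other cell types had peaks at 11 of 153 list entries (7.19%; 152 distinct genes, since VWF, without a peak, is on 2 lists), where random lists gave 14.6, and none of the 7 lists passed (adjusted permutation p 0.384 to 1). Megakaryocyte markers had 2 of 25, NFE2 and FLI1. Endothelial markers had 3 of 25, EGFL7 (8.42), ESAM (5.53) and ICAM2 (5.17). B-cell markers had 2 of 15, among them CD79A (7.44), and T-cell markers 2 of 19, LCK (4.05) and CD3G (4.82). The peaks counted for CD79A, LCK and CD3G lay at ends of ARHGEF1, HDAC1 and UBE4A. Neutrophil and monocyte markers had 1 of 26, TYROBP (6.27, also at an end of HCST), neuronal markers 1 of 21, GAD1 (4.79), and hepatocyte markers 0 of 22.

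The genes with most peaks in the gene or within 10 kb were PITPNM2 with 4 and a group of 13 genes with 3 each. To make up 10 names the shortest of those 13 were taken: ZFP36, HES1, TRIM28, ZNF625, PLEKHG2, PPP1R9B, ZNF263, TUBA4B and U2AF2. HES1 is a Notch target gene. ZFP36 and PLEKHG2 are neighbours and shared their strongest peak. The strongest peak counted for TRIM28 was 4279 bp away from it at ends of CHMP2A and UBE2M, and those of ZNF625, TUBA4B and U2AF2 lay at ends of ZNF136, DNAJB2 and EPN1.

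Peak density was lastly compared between chromosomes. Chromosome 19 had the most, 3.05 peaks per Mb (exact Poisson interval 2.61 to 3.55), against a mean of 0.548. The Mb were those used for random placement, without long intervals lacking an annotated gene, while peaks were counted everywhere. Densities of chromosomes with peaks in such intervals may thus be overstated. Chromosome 19 had a run of 15 peaks far from protein-coding genes (24930048 to 27145077). Without peaks on more than 2 times the median background its density was 2.27 (1.89 to 2.70), against a mean of 0.475. Of the 23 chromosomes 7 lay above and 8 below the mean of 0.548. Per 100 protein-coding genes (mean 7.83), 4 lay above: chromosomes 21 (33.5), 19 (11.6), 8 (11.2) and 10 (10.1). Another 6 lay below: 6, 7, 11, 13, 17 and X. On chromosome 21, 61 of the 80 peaks were in the ribosomal DNA. Without peaks on more than 2 times the median background, a setting chosen after seeing the data, chromosome 21 had 6.28 peaks per 100 genes, within its interval of the mean of 6.79. Chromosomes 19 (8.61), 8 (10.6) and 10 (9.26) were still above that mean and chromosome 2 (8.37) was now above it. Chromosomes 7, 13 and X were still below, chromosome 5 was now below, and chromosomes 6, 11 and 17 were not. In the peaks of higher significance chromosome 10 (4.50, mean 3.92) was no longer above, nor chromosomes 11 and 17 below. With peaks outside annotated genes only (mean 2.09 per 100 genes), chromosomes 19 (2.83), 8 (3.08) and 10 (2.45) were all within their intervals of the mean, chromosomes 21 (17.6) and 1 (2.76) were above, and 2, 6, 7 and X were below.

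**Figure D3:**
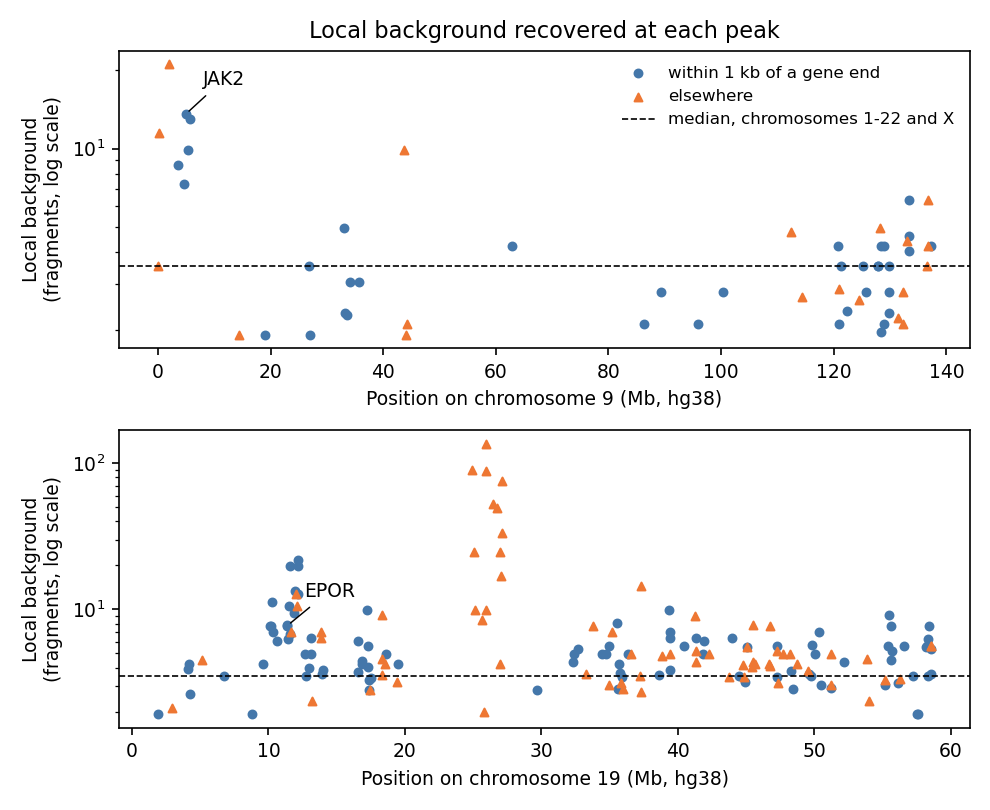
Local background in fragments (log scale) recovered at each peak along chromosomes 9 and 19, with position in Mb of hg38; circles are peaks within 1 kb of a gene end, triangles other peaks, and the dashed line is the median (3.52) of chromosomes 1 to 22 and X. The peaks of JAK2 and EPOR are marked, and sit among neighbours above that line.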

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

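Both tests in this part were chosen after the result was seen. Of the 1645 peaks, 81 lay on sequences that the comparisons by gene did not use, which is what drew attention to them. Scaffolds KI270733v1 and GL000220v1, which carry ribosomal DNA, held 51 peaks with a median fold of 2.33. Alternate loci held 16 peaks with a median fold of 4.67, mitochondrial DNA 4 with a median background of 11.1 fragments, and other sequences 10 with a median fold of 2.31. Peaks of the Vector library alone were not analysed here, so none of these could be set against a control list.

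The 51 scaffold peaks resemble 61 peaks in the ribosomal DNA of chromosome 21 (8203853 to 8471694), and together they are 112. Reads from many genomic copies that map to few reference copies may account for their high background, with a median 11.2 times that of the other peaks. A high background does not by itself account for an excess over it. Their median fold was lower, 2.23 against 4.72. Peaks on a higher background reach significance at a lower fold, so this difference does not bear on the explanation by copies. The biological explanation, binding of AM-ERG to ribosomal DNA, was not decided. Every listed peak exceeds its local background by selection, so the median fold of 2.23 does not bear on it, and without a peak list of the Vector cells it cannot be told apart from a bias shared by any precipitation.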

How the results depend on the processing

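No paired analysis was possible because each group has 1 sample and the labels give no replicate numbers. Not run, for want of a genome sequence and exons here, were all motif settings, the exon settings for ERG and the placement matched on GC content. Settings by fold, by raised background and by gene density were chosen after seeing the data. The cause of each change was not tested unless stated. Keeping the peaks of higher significance left 823 of all 1645 by construction. For shares, gene lists and chromosomes the upper 50% was taken among the 1564 peaks on chromosomes 1 to 22 and X. The share at gene ends was 53.6% within 500 bp and 67.5% within 3 kb, as a narrower or wider window implies, 70.8% with ends of all annotated genes, 67.8% without peaks of raised background and 68.8% in the upper 50% by fold. Its ratio to random placement was 10.0 with placement 10 to 100 kb from each peak, 17.7 in the peaks of higher significance and 20.6 without raised background, and 0 of 1000 placements came as high in each. The number of lists above random was 1 in the upper 50% by fold, and 2 to 4 in the other 7 settings. Stem and progenitor factors passed only by nearest gene end (adjusted permutation p = 0.0161). Chromosomes off the mean density numbered 12 to 15.

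Among lists that passed in no setting, the ratio to random crossed 1 in 16 cases. Heme and iron genes reached 1.01 unmatched, 1.69 by significance and 1.05 by fold. Deacetylases fell to 0.976 by significance and 0.898 by fold. Megakaryocyte markers reached 1.12 within 50 kb, 1.22 by nearest end and 1.49 by fold. B-cell markers had 0 at gene ends only, 0.766 within 50 kb and 0 by nearest end. T-cell markers had 0 at gene ends only, 0 by nearest end, 0 by significance and 0.891 by fold. Endothelial markers had 0.683 at gene ends only.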

Other observations

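Of the tests in this part, that of divergent transcripts was set before its result was seen. The others were chosen after, including the form in which the planned test at ERG was run. Peaks also lay at the ends of genes other than protein-coding ones. Ends of long non-coding RNA genes were within 1 kb of 305 peaks (19.5%, random placement 2.67%), of which 86 were away from protein-coding ends. For microRNA genes there were 28 such peaks (8 away from protein-coding ends), for small nuclear RNA genes 8 (7) and for tRNA genes 6 (5). For each of these biotypes 0 of 1000 random placements gave as many. The counts compared include peaks at protein-coding ends, and peaks away from those ends were not tested alone. Placements also treat peaks as separate, and a few loci carry the small counts: 6 of the 8 small nuclear RNA peaks and 3 of the 6 tRNA peaks each lay in 1 cluster. The cluster of 7 peaks at chromosome 17, 43246010 to 43300951, which holds those 6, lay at an array of 11 small RNA genes, with a median fold of 5.26 on a background of 14.1 fragments. The tRNA cluster, 3 peaks at chromosome 1, 161454494 to 161469630, had a median fold of 2.04 on a background of 17.6 fragments. Of the microRNA peaks, 4 of 28 lay in the run of raised background on chromosome 21 (8205582 to 8988656) that includes the ribosomal DNA. Genes with the biotype pseudogene had 12 peaks, a share of 0.767% against 1.57% at random, and 3 of 1000 placements gave as few. Those with the biotype transcribed pseudogene went the other way, with 28 peaks (23 away from protein-coding ends), 1.79% against 0.210% at random, and 0 of 1000 placements gave as many.

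Among 147 families of genes with a shared symbol stem, 0 passed the permutation test with more genes with a peak than random lists and 1 passed with fewer. That family was the olfactory receptors, with 0 of 392 genes against 29.4 expected (adjusted permutation p = 0.0294, from the smallest p possible). Families of WD-repeat genes (14 of 58, 5.79 expected, adjusted permutation p = 0.235) and keratins (0 of 55, 5.09 expected, adjusted permutation p = 0.382) did not pass. Nor did families with the symbol stem RPS (8 of 43, 3.68 expected, adjusted permutation p = 0.624) or RPL (8 of 52, 4.59 expected, adjusted permutation p = 0.888). These take in more genes than the ribosomal protein list, and the adjustment was over 147 families.

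Gene ends with a peak may mostly be starts. Divergent transcripts, which arise beside gene starts, were annotated for 567 genes, and 52 of these had a peak at just 1 end. It was the end beside the divergent transcript in 51, or 98.1% (Wilson interval 89.9 to 99.7%). Reads from the ERG sequence carried in the vector could appear as peaks over ERG exons. Counted over the whole gene in place of its exons, a change made after the data were seen, ERG held 1 peak. This argues against called peaks over many of its exons. Reads too few to be called as a peak would not show in the list, so such reads are not excluded. Whether that peak overlaps an exon was not examined.

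Local background was raised over runs of neighbouring peaks on chromosome 19 (10106325 to 11505821, median 7.74 fragments, and 11597524 to 12163506, median 12.7) and chromosome 9 (2016782 to 5629264, median 11.4), which include EPOR and JAK2. With the peaks of other raised runs left out, a running median as high as 11.5, the lower of the maxima on these chromosomes, arose by chance in 29 of 1000 random orders of the peaks (highest 19.7). The segment with EPOR, at a median of 7.74, was below that level and was not itself tested against chance. More control reads at gene ends in general would not account for the raised runs, since outside such runs the background at gene ends was 1.11 times that of other peaks. Extra copies of these segments in F36P may contribute: with runs found on every other peak, the 21 peaks in between, which also took in some of chromosome 19 outside the segments, had 2.38 times the background elsewhere. First forms of this test and of that on gene ends were set aside because they used the peaks that had defined the runs. The present test of copies shows a regional rise without separating copy number from mappability or other regional causes.

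The excess of peaks at erythropoietin, JAK and STAT pathway genes did not rest on EPOR and JAK2 alone. Without the peaks of their segments of raised background 11 of 31 genes had a peak (2.89 expected, adjusted permutation p = 0.0038). Only EPOR and JAK2, of the 13 genes with a peak, could be lost in this way. The count was therefore fixed beforehand and is no test of a cause. Peaks at the starts of active genes in general could produce the excess too, and this stays open. The pathway and ribosomal protein lists, 13 and 10 of 31 genes, gave p = 0.5996 in a two-sided Fisher exact test, which does not show that they are alike. In the wider RPS and RPL families, grouped by symbol alone, 18.6% and 15.4% of genes had a peak, and gene activity was not measured here. A role of ERG specific to this pathway is therefore a hypothesis that this list cannot decide.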
